A study of Mus musculus with 9 samples.

How the data were processed

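RNA sequencing was carried out on retinas of Balb/c mice in a light damage model, with 9 libraries in 3 groups of 3, namely control, light damage, and light damage with A74. The labels do not spell out what A74 is, its dose or vehicle, or how long the light lasted, and the series title concerns inhibition of P2RX7, an ATP-gated ion channel. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

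The authors deposited 1 table of read counts per gene with a column per library and the Ensembl identifier, symbol and biotype of 55414 genes. The deposited counts are whole numbers that were not normalised, as judged from the values, whose totals differ between libraries. RSEM 1.3.1, Bowtie2, DESeq2 1.4.5 and the mouse build GRCm39 are named, per the submitters' processing notes, without saying what each was used for. Whether the whole numbers are rounded RSEM estimates, whether strand was used and which annotation release was counted are not given in the sources used here. An estimate of that kind splits reads between near-identical genes, and without strand information reads of overlapping and antisense genes cannot be told apart, so such genes are uncertain. The reference at hand was of another build, so no coordinates were used, and gene names are those of the table itself.

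Library totals ran from 14788000 to 18740400 counts. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17272 genes. Because that filter asks for the count in 3 libraries, genes that were high in 2 light damage libraries alone were left out. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, in 1 fit of the 9 libraries without covariates. A gene was called at an adjusted p under 0.05, and every adjusted p given for a gene comes from this test unless another tool is named. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. Levels are CPM, read counts scaled to library size, with TMM factors. Log2 CPM used a prior count of 2.

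Gene lists and cell type markers, 31 in all, were fixed before the data were examined, and those with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Camera was rerun with a correlation estimated for each list, and fry was run as a directional test. Beside the count of a list's members called over all genes stands the count adjusted over the list alone. Genes named in the text follow a rule that was also fixed before the data were examined. It takes the 10 largest log2 fold changes in each direction (5 for A74 against control) among called genes with a mean of at least 1 CPM in a group and no overlap between the groups of libraries, up to 4 members of each list with the smallest adjusted p, and 11 genes named in every comparison. The rule left out predicted genes, clone names and near-identical multigene copies. Which symbols counted as such copies was decided after the ranked genes had been seen, and removed 7SK, Fam177a2, Lilrb4b, Ifi202b and the Dynlt1 and Tmem181 families. The text names a part of the genes the rule gives.

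Sex-linked transcripts and genes of anterior eye tissue were found to differ between libraries within groups after the data had been examined. A list of 8 anterior tissue genes (Ltbp2, Fbln1, Optc, Cldn2, Mfap4, Gpx3, Vcan and Bmp4), written after the data were seen, split the libraries at the widest gap of their summed CPM on the log2 scale. This split is called the tissue set. Within-set values come from a fit with a mean for each group and tissue set, where a cell holding 1 library borrows its spread from the others. Fits with tissue set, Y transcripts or both as terms, and a fit without light damage replicate 3 and A74 replicate 1, were also added after the data were seen.

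Alternatives fixed in advance were DESeq2's size factors in edgeR, no count filter, DESeq2 1.42.0, a fit of the 2 groups compared alone, the replicate number as a block, a 2-fold minimum change, and leaving out each library in turn. The share of the light change left with A74 was the summed log2 change of A74 against control over that of light damage against control, over light-changed genes signed by their light direction. A cross-fitted value chose the genes without 1 light damage and 1 control library and measured the change in those, over 9 combinations. Because light damage against control and A74 against light damage share the light damage libraries, counts were simulated 20 times with no effect in any group and 20 times with A74 equal to light damage.

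The tests were run on simulated data made from the real means, library sizes and dispersions of 17272 genes, with 200 genes changed. In the simulation of light damage against control, 49.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and 20 of 17036 unchanged genes were called. For A74 against light damage the shares were 58.2%, 85.1% and 97.0%, with 21 of 17037 unchanged genes called. For A74 against control they were 56.7%, 76.1% and 93.9%, with 14 of 17037 unchanged genes called. All 3 lists shifted in each simulation were called with either correlation. In the third simulation 1 list that had not been shifted was called with the preset correlation. Genes were drawn independently, so these simulations do not cover lists of correlated genes. The correlation estimated for interferon-stimulated genes was 0.91 in light damage against control. No pair of replicates agreed within sampling noise, since chi-square per degree of freedom ran from 2.52 to 15.7 over the pairs of a group.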

Results

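The transcriptome of the retina was measured in control mice, after light damage, and after light damage with A74, in 3 libraries per group with 14788000 to 18740400 counts each. Light damage in albino Balb/c mice is a model of photoreceptor degeneration. The series asks how A74 alters the response of the retina to light, and its title names P2RX7 and the cGAS-STING pathway of cytosolic DNA sensing.

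Libraries of a group differed in sex-linked transcripts and in a list of genes taken here to mark anterior eye tissue. Xist, the transcript of the inactive X chromosome, had 22253 counts in control replicate 3 and 17227 to 18172 in the 3 A74 libraries, against 1 to 7 in the other 5 libraries. Ddx3y, Kdm5d, Eif2s3y and Uty on the Y chromosome together had 4249 to 5832 counts in replicates 1 and 2 of control and light damage and 0 counts in the other 5 libraries. No light damage library was high in Xist and all 3 A74 libraries were, so this difference lies along the comparison of A74 with light damage. Light damage replicate 3 had neither Xist above 1 count nor any Y-linked count. Anterior tissue genes summed to 138 to 275 CPM in replicates 1 and 2 of control and light damage and in A74 replicate 1, and to 12.5 to 15.9 CPM in the other 4 libraries. Lens genes summed to 1023 CPM in A74 replicate 1 and to at most 188 CPM elsewhere. They did not follow the split by anterior tissue genes. Control replicate 1, high in anterior tissue genes, had 39.1 CPM of lens genes, and A74 replicate 2, low in them, had 168 CPM. The anterior tissue list was written after the data were seen, and the source of its RNA was not tested.

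**Figure D1:**
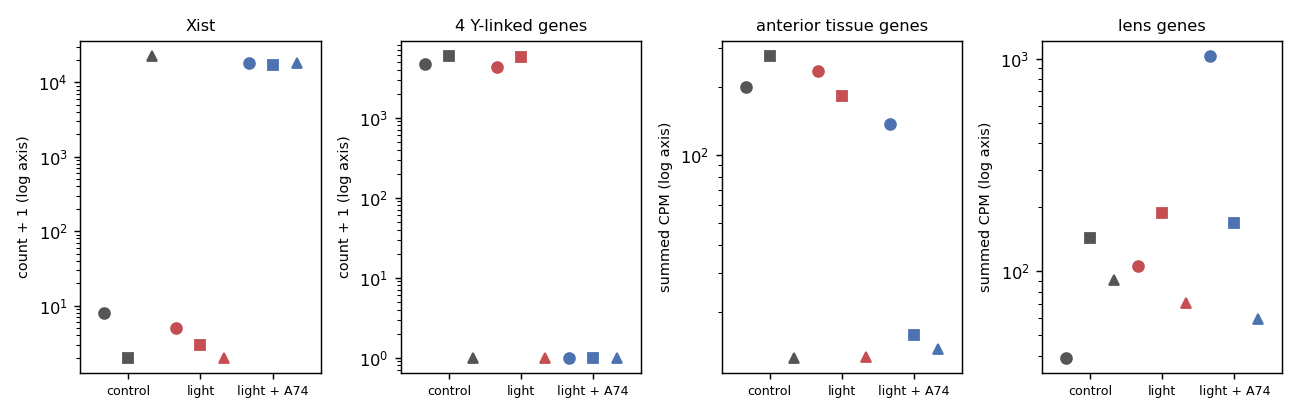
Sex-linked, anterior tissue and lens transcripts in each of the 9 libraries (circle, square and triangle are replicates 1, 2 and 3), as counts plus 1 or summed CPM on log axes. Xist is high in control replicate 3 and all 3 A74 libraries, and the 4 Y-linked genes are at 0 counts in the same libraries and in light damage replicate 3.

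Light damage was first compared with control. Most markers of microglia and macrophages and all listed genes of reactive gliosis rose. Most interferon-stimulated, complement and antigen presentation genes also rose, while most rod photoreceptor genes fell. Trem2, a microglial lipid receptor, went from 1.57 ± 0.205 to 10.2 ± 3.73 CPM (SD, n = 3), a log2 fold change of 2.69 (SE 0.27, edgeR adjusted p = 1.71e-05). Gfap, the intermediate filament of reactive glia, rose from 21.5 ± 2.76 to 97.1 ± 40.8 CPM (SD, n = 3, edgeR adjusted p = 0.00588). Rpgrip1, a ciliary protein gene of photoreceptors, fell by 0.77 on the log2 scale (SE 0.08, edgeR adjusted p = 1.32e-05). In all, edgeR's quasi-likelihood test called 4452 of 17272 genes after Benjamini-Hochberg adjustment, 2247 higher and 2205 lower, of which 482 and 133 changed at least 2-fold.

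Among microglia and macrophage markers, 19 of 22 rose and none fell, or 21 adjusted over the list alone, with a median log2 fold change of 2.48. C1qa, a subunit of the complement initiator C1q, rose by 2.61, Lgals3, a galectin of phagocytes, by 2.57, and Aif1, which encodes the microglial marker IBA1, by 2.65 on the log2 scale. The list was called by camera (adjusted p = 8.39e-17), with adjusted p = 0.129 with an estimated correlation. The scavenger receptor gene Msr1 had the largest rise the rule gave, at 7.31 (SE 0.61, edgeR adjusted p = 6.46e-05), and Ms4a6d rose by 4.69. Of the complement genes 9 of 12 rose, also 9 adjusted over the list alone, among them C3ar1, the C3a receptor gene (5.56, SE 0.52), and C1qc (3.63, SE 0.33). Complement had camera adjusted p = 5.12e-08 and adjusted p = 0.150 with an estimated correlation. Of the neutrophil and T cell markers 1 each was measured, and Csf3r, the measured neutrophil marker, rose by 2.08. The other listed neutrophil markers were under the count filter. They had at most 8 counts in a library (Camp), with S100a8 at most 1 and Ly6g 0. The rise of Csf3r alone therefore does not show neutrophils.

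All 19 genes of reactive gliosis and the neurotrophic response rose, also 19 adjusted over the list alone, with a median of 2.12 on the log2 scale (camera adjusted p = 8.39e-17, adjusted p = 0.129 with an estimated correlation). Edn2, an endothelin made by stressed photoreceptors, rose from 4.86 ± 0.368 to 31.1 ± 3.06 CPM (SD, n = 3, edgeR adjusted p = 1.5e-08). Cebpd, a transcription factor of inflammation, rose by 2.63, Osmr, the oncostatin M receptor gene, by 1.77 and the metalloreductase gene Steap4 by 4.98. Of the Müller glia markers 8 of 10 rose, also 8 adjusted over the list alone (camera adjusted p = 4.28e-06, adjusted p = 0.150 with an estimated correlation). Slc1a3, the glial glutamate transporter gene, rose by 0.64, Rlbp1, which encodes a retinoid-binding protein, by 0.48 and the carbonic anhydrase gene Car14 by 0.59.

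Rod photoreceptor genes fell in 21 of 28 cases and none rose, or 25 adjusted over the list alone, with a median log2 fold change of -0.55 (camera adjusted p = 3.23e-13, adjusted p = 0.223 with an estimated correlation). Besides Rpgrip1, the log2 fold change was -0.67 for the rod transcription factor gene Nrl and -0.68 for the rod channel gene Cngb1. Sag, chosen after its values were seen, had a log2 fold change of 0.11 (edgeR adjusted p = 0.450). Of 11 cone genes 3 rose and none fell, also 3 adjusted over the list alone, among them Gnb3 (0.55) and Gngt2 (0.57), while the cone opsin gene Opn1mw had -0.20 (edgeR adjusted p = 0.111). Opn1mw lay between -0.25 and -0.07 in fits that leave out 1 library, and was called without light damage replicate 3 (edgeR adjusted p = 0.0435). The cone list was not called (camera adjusted p = 0.997). Retinal ganglion cell markers rose in 8 of 12 cases, also 8 adjusted over the list alone, with Sncg at 0.51 (camera adjusted p = 0.000202, adjusted p = 0.280 with an estimated correlation). Bipolar markers rose in 4 of 11 cases, with 4 higher and 1 lower adjusted over the list alone, such as Pcp2 (0.48), amacrine markers in 2 of 10 and horizontal markers in 1 of 5. These 3 lists were not called (camera adjusted p = 0.317, 0.0847 and 0.443). The endothelial and pericyte list was called with 2 of 12 higher, also 2 adjusted over the list alone, among them the VEGF receptor gene Kdr at 0.82 (camera adjusted p = 0.0183, adjusted p = 0.158 with an estimated correlation). None of 9 pigment epithelium or 15 lens genes was called by edgeR, also 0 adjusted over the list alone.

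Interferon-stimulated genes rose in 26 of 27 cases, also 26 adjusted over the list alone, with a median of 2.74 on the log2 scale (camera adjusted p = 5.13e-10, adjusted p = 0.315 with an estimated correlation, fry adjusted p = 0.0525). Gbp2, a guanylate-binding protein gene, rose by 2.42, Ifi27l2a by 3.22 and Dhx58, a helicase of RNA sensing, by 1.76. Ifi44l had 231 counts in the light damage group and 3 in control, a ratio of 68.7 with a 95% exact counting interval of 23.2 to 335. That interval pools the reads of a group and leaves out the spread between libraries. The edgeR test, which includes that spread, called Ifi44l (edgeR adjusted p = 0.00576). Antigen presentation genes rose in 12 of 14 cases, also 12 adjusted over the list alone, with Tap1, a peptide transporter gene, at 1.77 and the immunoproteasome gene Psmb9 at 2.82 (camera adjusted p = 2.47e-07, adjusted p = 0.150 with an estimated correlation). Of the cGAS-STING components, 1 of 6 was called, also 1 adjusted over the list alone, and that was a fall of 0.39 in Irf3, the transcription factor downstream of STING (SE 0.07, edgeR adjusted p = 0.000764). Cgas had a log2 fold change of 0.29 (edgeR adjusted p = 0.740), Sting1 0.34 (edgeR adjusted p = 0.565) and Tbk1 -0.01 (edgeR adjusted p = 0.910). The cGAS-STING list was not called (camera adjusted p = 0.997). Cgas had at most 16 and Sting1 at most 31 counts in a library, and the SE of their log2 fold changes was 0.53 and 0.38. Ifnb1 had 0 counts in all 9 libraries, and Il1b and Ccl2 were under the count filter. So were 4 of the 10 listed cGAS-STING components, among them Ifi204 and Zbp1, chosen after their values were seen, which reached 111 and 69 counts in a library but did not pass the filter's requirement of 3 libraries.

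P2rx7 rose from 0.469 ± 0.256 to 1.61 ± 0.558 CPM (SD, n = 3), a log2 fold change of 1.74 (SE 0.42, edgeR adjusted p = 0.00648), from 3 to 12 counts per control library and 16 to 36 per light damage library. In its list of purinergic genes 7 of 17 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.200 with an estimated correlation). P2ry6, a UDP receptor gene of microglia, rose by 2.48, and Nt5e, the gene of the adenosine-producing enzyme CD73, fell by 0.89. Casp1 (3.63) and Pycard (1.90) were the 2 of 8 inflammasome genes that rose, or 3 adjusted over the list alone (camera adjusted p = 0.0412, adjusted p = 0.211 with an estimated correlation). Of 9 cytokine, chemokine and NF-kB genes 8 rose and 1 fell, also 8 and 1 adjusted over the list alone, with the adhesion gene Vcam1 at 1.98 and Nfkbia at 1.01 (camera adjusted p = 3.85e-05, adjusted p = 0.129 with an estimated correlation). Tnfaip3, chosen after its values were seen, was the one that fell, with a log2 fold change of -0.74.

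Cell cycle genes rose in 9 of 16 cases, or 11 adjusted over the list alone (camera adjusted p = 0.000148, adjusted p = 0.129 with an estimated correlation). Mki67 had 190 counts in the light damage group against 2 in control, a ratio of 84.7 with a 95% exact counting interval of 23.1 to 705. This interval too leaves out the spread between libraries, and the edgeR test called Mki67 (edgeR adjusted p = 2.32e-05). Cdk1 rose by 3.46. Antioxidant and metallothionein genes rose in 8 of 14 cases, or 9 adjusted over the list alone, with Mt1 at 1.55 (SE 0.10, edgeR adjusted p = 1.51e-07) and the heme oxygenase gene Hmox1 at 1.80 (camera adjusted p = 9.93e-06, adjusted p = 0.129 with an estimated correlation). Apoptosis and necroptosis genes rose in 5 of 15 cases, also 5 adjusted over the list alone, among them Casp8 (1.53), Tnfrsf1a (1.51) and Cdkn1a (1.49) (camera adjusted p = 0.00361, adjusted p = 0.129 with an estimated correlation). Immediate-early genes rose in 10 of 12 cases, or 12 adjusted over the list alone, with Junb at 1.41, Fosb at 1.46 and Atf3 at 0.85 (camera adjusted p = 1.87e-08, adjusted p = 0.129 with an estimated correlation). The largest falls included Tgm7 (-2.20), Dleu7 (-1.51) and Cmah (-1.47).

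Within the tissue set with more anterior RNA, 2 light damage against 2 control libraries, the mean log2 change of interferon-stimulated genes was 3.22, and in the other set of 1 against 1 it was 1.20. In the same order, that of microglia markers was 2.47 and 2.04, that of gliosis genes 2.33 and 2.00, that of Müller glia markers 0.50 and 0.41, and that of rod genes -0.71 and -0.21. Cdkn1a had 2.01 in the first set and 0.17 in the second, with edgeR adjusted p = 0.0844 for the difference. Among control and light damage libraries, the tissue sets also split by Y-linked counts, so differences between the sets cannot be assigned to anterior RNA. The count of called genes was 2818 without light damage replicate 2.

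**Figure D2:**
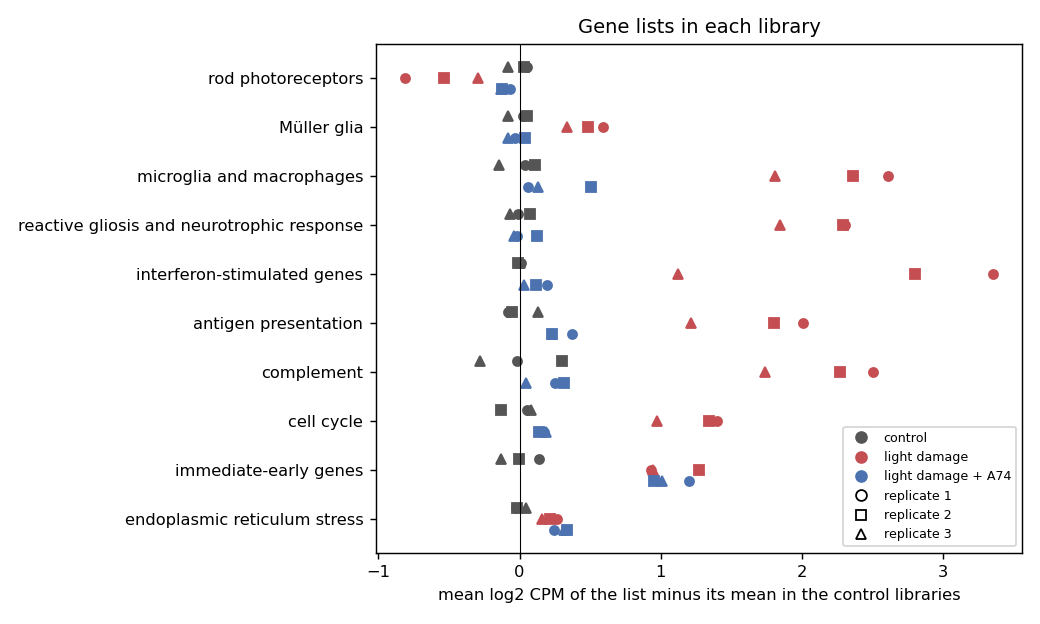
Mean log2 CPM of 10 gene lists in each library, relative to the mean of the control libraries (colour is the group, and circle, square and triangle are replicates 1, 2 and 3). Interferon-stimulated genes lie at 3.35, 2.80 and 1.12 in light damage replicates 1, 2 and 3 and at 0.03 to 0.19 with A74, whereas immediate-early genes lie at 0.93 to 1.27 in all 6 light-exposed libraries.

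The second comparison asked how A74 changed the light-damaged retina. Most microglia and interferon-stimulated genes and all listed gliosis genes were lower with A74 than with light damage alone, and most rod genes were higher. Trem2 fell by 2.17 (SE 0.26, edgeR adjusted p = 0.000112), to 2.27 ± 0.48 CPM (SD, n = 3). Gfap fell by 2.49 (SE 0.35, edgeR adjusted p = 0.00587), to 17.3 ± 1.28 CPM (SD, n = 3), and Rpgrip1 rose by 0.49 (SE 0.08, edgeR adjusted p = 0.000732). The edgeR test called 3153 of 17272 genes, 1566 higher and 1587 lower with A74, of which 61 and 420 changed at least 2-fold. The 3 A74 libraries were all high in Xist and had no Y-linked counts, while 2 of the 3 light damage libraries had Y-linked counts. With Y transcripts as a term, which was chosen after seeing the data, the count was 745.

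Microglia and macrophage markers fell in 20 of 22 cases with a median of -2.11 on the log2 scale, or 22 adjusted over the list alone (camera adjusted p = 8.93e-20, adjusted p = 0.126 with an estimated correlation). The log2 fold change was -2.58 for Gpnmb, -2.35 for Lgals3, -2.05 for C1qa and -2.22 for Aif1. Complement genes fell in 10 of 12 cases, or 11 adjusted over the list alone, with C3ar1 at -3.56 (camera adjusted p = 3.55e-10, adjusted p = 0.126 with an estimated correlation). All 19 gliosis genes fell, also 19 adjusted over the list alone (camera adjusted p = 7.64e-20, adjusted p = 0.125 with an estimated correlation). Edn2 fell by 2.05 (SE 0.14, edgeR adjusted p = 4.21e-07), and the log2 fold change was -2.31 for Cebpd, -1.53 for Osmr, -5.25 for Steap4 and -3.65 for Bcl3. Of the Müller glia markers 8 of 10 fell and 1 rose, the same counts adjusted over the list alone, with Slc1a3 at -0.69, Rlbp1 at -0.43 and Car14 at -0.70 (camera adjusted p = 3.72e-07, adjusted p = 0.126 with an estimated correlation). Abca8a, chosen after its values were seen, was the one that rose (0.19).

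Rod photoreceptor genes rose in 21 of 28 cases and none fell, or 23 adjusted over the list alone, with a median of 0.41 on the log2 scale (camera adjusted p = 1.36e-12, adjusted p = 0.252 with an estimated correlation). Besides Rpgrip1, Nrl rose by 0.55, Cngb1 by 0.51 and Nr2e3, a rod fate transcription factor gene, by 0.58. Bipolar markers fell in 5 of 11 cases, or 7 with 1 higher adjusted over the list alone (camera adjusted p = 0.00446, adjusted p = 0.235 with an estimated correlation). One of 12 retinal ganglion cell markers fell, Isl1 by 0.46, or 5 adjusted over the list alone (camera adjusted p = 0.00304, adjusted p = 0.359 with an estimated correlation, fry adjusted p = 0.0512). Endothelial and pericyte markers fell in 4 of 12 cases, also 4 adjusted over the list alone, with Kdr at -0.73 (camera adjusted p = 0.00446, adjusted p = 0.126 with an estimated correlation). The amacrine list was called lower with 0 of 10 members called, also 0 adjusted over the list alone (camera adjusted p = 0.0193, adjusted p = 0.335 with an estimated correlation). Opn1mw had a log2 fold change of 0.23 (edgeR adjusted p = 0.0784), and was called without light damage replicate 3 (edgeR adjusted p = 0.0257). Of 11 cone genes 1 rose and 1 fell, and of 5 horizontal genes 1 fell, the same adjusted over the list alone. The cone and horizontal lists were not called (camera adjusted p = 0.991 and 0.353).

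Interferon-stimulated genes fell in 22 of 27 cases, or 26 adjusted over the list alone, with a median of -2.51 (camera adjusted p = 8.84e-12, adjusted p = 0.280 with an estimated correlation, fry adjusted p = 0.0530). The log2 fold change was -4.52 for Ifi27l2a, -2.36 for Gbp2, -1.38 for Ifi35 and -1.86 for Dhx58. Antigen presentation genes fell in 11 of 14 cases, also 11 adjusted over the list alone, with Tap1 at -1.80 and Psmb9 at -1.86 (camera adjusted p = 3.33e-08, adjusted p = 0.126 with an estimated correlation). Irf3 rose by 0.46 (SE 0.07, edgeR adjusted p = 0.000442) and was the 1 of 6 cGAS-STING components called, also 1 adjusted over the list alone. Cgas had -0.89 (edgeR adjusted p = 0.293), Sting1 -0.58 (edgeR adjusted p = 0.328) and Tbk1 0.08 (edgeR adjusted p = 0.465), and the list was not called (camera adjusted p = 0.854). Cytokine, chemokine and NF-kB genes fell in 8 of 9 cases and 1 rose, the same adjusted over the list alone, with Vcam1 at -1.90 (camera adjusted p = 3.37e-05, adjusted p = 0.126 with an estimated correlation). Tnfaip3, chosen after its values were seen, was the one that rose (0.79).

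P2rx7 was lower by 1.30 on the log2 scale with A74 (SE 0.40, edgeR adjusted p = 0.0325), at 0.648 ± 0.169 CPM (SD, n = 3) and 8 to 14 counts per library. This call was lost with DESeq2 (adjusted p = 0.0804), without any 1 of 5 libraries (light damage replicate 1 or 2, or A74 replicate 1, 2 or 3, with a highest edgeR adjusted p of 0.166), with tissue set as a term (edgeR adjusted p = 0.0690), with Y transcripts as a term (edgeR adjusted p = 0.370), and with both terms (edgeR adjusted p = 0.495). Its log2 fold change lay between -1.53 and -1.04 in the 9 fits that leave out 1 library, and was -0.88 with Y transcripts and -0.73 with both terms. Purinergic genes fell in 5 of 17 cases and 1 rose, or 7 and 1 adjusted over the list alone, with P2ry6 at -2.28 (camera adjusted p = 0.00808, adjusted p = 0.186 with an estimated correlation). Of 8 inflammasome genes 3 fell, or 4 adjusted over the list alone, with Casp1 at -3.30 and Pycard at -2.20 (camera adjusted p = 0.00446, adjusted p = 0.126 with an estimated correlation). The value of Casp1 was -5.41 without A74 replicate 2. Casp1 and Pycard lost their calls with Y transcripts as a term (edgeR adjusted p = 0.0631 and 0.0694) and with tissue set added to it (0.0917 and 0.135). Cell cycle genes fell in 6 of 16 cases, or 7 with 1 higher adjusted over the list alone, with Cdk1 at -3.01 (camera adjusted p = 0.00446, adjusted p = 0.186 with an estimated correlation). Antioxidant genes fell in 9 of 14 cases, or 11 adjusted over the list alone, with Mt1 at -1.13 and Hmox1 at -1.63 (camera adjusted p = 3.35e-07, adjusted p = 0.126 with an estimated correlation). Of 15 apoptosis and necroptosis genes 3 fell, also 3 adjusted over the list alone, among them Tnfrsf1a (-1.51), and the list was not called (camera adjusted p = 0.0837).

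Genes that were higher with A74 than with light damage alone included Nr4a3, a nuclear receptor gene induced by stimulation (2.98, SE 0.32, edgeR adjusted p = 9.37e-05), Atf4, the transcription factor gene of the integrated stress response (0.57, SE 0.07, edgeR adjusted p = 0.000152), and the clock gene Per1 (0.56, SE 0.07, edgeR adjusted p = 0.000152). The immediate-early list was not called (camera adjusted p = 0.876), with 2 of 12 higher and 1 lower, the same adjusted over the list alone. These were Jun (0.35), Atf3 (0.41) and Junb (-0.43), and each call was lost without A74 replicate 2 or 3, with a highest edgeR adjusted p of 0.0881, 0.143 and 0.120. Those of Atf3 and Junb were also lost without light damage replicate 1 or 2. Endoplasmic reticulum stress genes rose in 2 of 11 cases, also 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.204).

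With Y transcripts as a term 41 of the 60 named called genes stayed past the threshold. Gfap then had -2.02 (edgeR adjusted p = 0.0519), Nrl 0.49 (0.0743), Cngb1 0.43 (0.0833), Ifi35 -1.03 (0.0664), Junb -0.30 (0.288) and Atf3 0.48 (0.0942), while Edn2 had -2.04 (edgeR adjusted p = 7.39e-06) and Trem2 -1.63 (edgeR adjusted p = 0.00243). With both terms Aif1 (-1.60, edgeR adjusted p = 0.0598), P2ry6 (-1.98, 0.0644) and Dhx58 (0.0592) also lost their calls. Within the tissue set with more anterior RNA, 1 A74 against 2 light damage libraries, the mean log2 change was -3.14 for interferon-stimulated genes, -2.52 for microglia markers and 0.59 for rod genes. In the other set, 2 A74 against 1 light damage library, it was -1.12, -1.48 and 0.17. The count of called genes was 1717 and 1731 without light damage replicates 1 and 2, and 1815 and 1777 without A74 replicates 2 and 3.

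**Figure D3:**
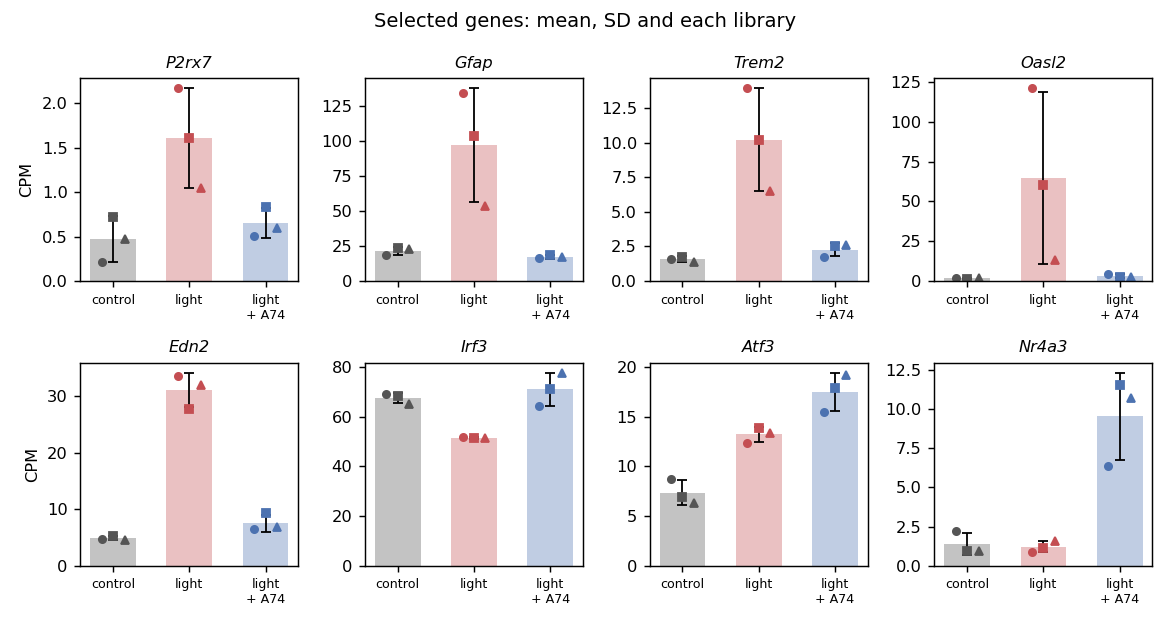
CPM of 8 genes by group, with bars for the mean, error bars for the SD of 3 libraries, and points for each library (circle, square and triangle are replicates 1, 2 and 3). Gfap lies at 97.1 CPM after light damage and 17.3 CPM with A74, whereas Nr4a3 lies at 1.21 and 9.54 CPM.

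Light-changed genes were then followed into the A74 group. Of 2247 genes higher after light damage, 1259 were called lower with A74 than with light damage alone and 4 were called higher. Of 2205 genes lower after light damage, 1021 were called higher with A74 and 0 were called lower, so that 2280 genes moved back. Independent lists of these sizes would overlap in 206 and 200 genes. Both comparisons share the light damage libraries. In 20 simulations with no effect in any group a mean of 0.10 genes moved back, or 0.70 with A74 equal to light damage. Genes were drawn independently there, without changes shared across a library. The simulations therefore cannot show how much overlap such shared changes would give. Across genes, which are not independent replicates, the fold changes of the 2 comparisons correlated at -0.75, against a mean of -0.49 in simulations without effects. Their covariance was -0.22, against -0.04 in those simulations, a difference of -0.18. The 3 light damage libraries could not be divided into 2 parts of at least 2, and part of the overlap may come from sharing them. The count of genes that moved back was 660 with Y transcripts as a term, 1257, 1226 and 3478 without light damage replicates 1, 2 and 3, and 1461 and 1480 without A74 replicates 2 and 3.

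Over the 4452 light-changed genes, 24.5% of the light change was left with A74 (SD 2.93 over 3 libraries). The A74 libraries lay at 23.1%, 28.3% and 23.4% of the mean light change, and light damage replicates 1, 2 and 3 at 119%, 107% and 73.9%. The cross-fitted share had a median of 20.6% over 9 combinations, from 14.4% to 31.4%. With Y transcripts as a term the share was 41.6%.

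**Figure D4:**
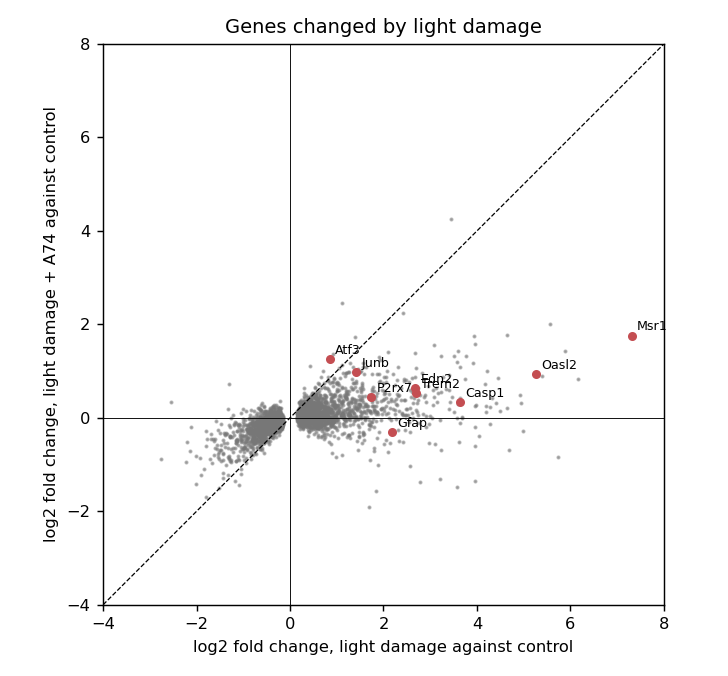
Log2 fold change of the 4452 genes called in light damage against control (x axis) and of the same genes in A74 against control (y axis), with the dashed line where both are equal and 9 genes in red. P2rx7 lies at 1.74 on the x axis and 0.44 on the y axis, and Atf3 at 0.85 and 1.25.

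The third comparison set the retina with light damage and A74 against control. Of 12 immediate-early genes 7 were called higher with A74 than in control, as was Atf4. No gene of the microglia, gliosis, interferon-stimulated or rod lists was called. The test shares 1 fit over all 9 libraries, so scatter among the light damage libraries enters it and can hide differences in these lists. Interferon-stimulated genes, for example, had list means of 3.35, 2.80 and 1.12 in light damage replicates 1, 2 and 3. The absence of calls therefore does not show a full return to control. Atf3, a stress-induced transcription factor gene, rose from 7.34 ± 1.26 to 17.5 ± 1.91 CPM (SD, n = 3), a log2 fold change of 1.25 (SE 0.13, edgeR adjusted p = 0.000189). Nr4a3 rose by 2.81 (SE 0.32, edgeR adjusted p = 0.00116), Sik1, a salt-inducible kinase gene, by 1.12 (SE 0.12, edgeR adjusted p = 0.000189) and Atf4 by 0.69 (SE 0.07, edgeR adjusted p = 0.000205). The edgeR test called 154 of 17272 genes, 102 higher and 52 lower, and 16 of them changed at least 2-fold. Of the 154, 141 had the same direction in light damage against control, a comparison that shares the control libraries.

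Immediate-early genes rose in 7 of 12 cases, or 12 adjusted over the list alone (camera adjusted p = 1.02e-17, adjusted p = 0.0631 with an estimated correlation). Jun rose by 0.64, Junb by 0.97 and Ier2 by 0.54, and the immediate-early transcription factor gene Egr3, which is outside the list, by 2.54. The list's mean log2 change was 1.28 within the tissue set with more anterior RNA and 1.24 in the other set. Endoplasmic reticulum stress genes rose in 2 of 11 cases, Atf4 and Herpud1 (0.33), or 6 adjusted over the list alone (camera adjusted p = 1.33e-05, adjusted p = 0.0716 with an estimated correlation). Per1 rose by 0.41 and the NF-kB inhibitor gene Nfkbia by 0.57. The log2 fold change was -0.78 for Kif15, a mitotic kinesin gene, and -0.49 for the transporter gene Slco4a1.

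P2rx7 had a log2 fold change of 0.44 (SE 0.48, edgeR adjusted p = 0.708), and 0.12 to 0.90 in fits that leave out 1 library. Gfap had -0.31 (edgeR adjusted p = 0.747), and 0.08 with Y transcripts as a term. Aif1 had 0.43 (edgeR adjusted p = 0.686) and Irf3 0.07 (edgeR adjusted p = 0.658). No gene of the microglia, gliosis, interferon-stimulated, complement, antigen presentation, Müller glia or rod lists was called, and 1 gliosis gene was called adjusted over the list alone. Camera called the rod list lower (adjusted p = 0.0455, adjusted p = 0.936 with an estimated correlation), the lens list higher (adjusted p = 0.00552, adjusted p = 0.936 with an estimated correlation) and the pigment epithelium list lower (adjusted p = 0.0109, adjusted p = 0.936 with an estimated correlation), with 0 genes called in each. Lens genes stood at 1023 CPM in A74 replicate 1.

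The count of 154 genes changed with the libraries and the test. It was 28 and 35 without control replicates 1 and 2, 21, 36 and 306 without A74 replicates 2, 3 and 1, 312 and 416 without light damage replicates 1 and 3, 718 without a count filter, 296 with DESeq2, 558 in a fit of the 2 groups alone and 96 with Y transcripts as a term. Lists called went from 5 to 2 without control replicate 1 and to 3 without A74 replicate 3. Of the 14 named called genes, Nr4a3, Atf3, Sik1, Jun, Junb and Atf4 kept their call without any 1 of the 9 libraries. With Y transcripts as a term, 6 of the 14 lost it, namely Herpud1 (edgeR adjusted p = 0.0693), Nfkbia (0.0675), Per1 (0.0675), Kif15 (0.0725), Slco4a1 (0.145) and Papolb (0.139). Of single libraries, Ier2 lost it without control replicate 1 or 2 or A74 replicate 2 (highest edgeR adjusted p = 0.104), Egr3 without A74 replicate 2 (0.0582), Per1 without control replicate 2 or A74 replicate 2 or 3 (0.129), and Herpud1 and Kif15 without control replicate 1 or 2 or A74 replicate 2 or 3 (0.180 and 0.0955). Nfkbia lost it without any of 6 libraries, among them the 3 control libraries (0.197), and Slco4a1 without any of 5, among them control replicates 1 and 2 (0.234), and Papolb without any of 6, among them the 3 control libraries (0.180). With the replicate number as a block, Papolb and Slco4a1 lost it too. The fold changes kept their direction in each of these fits, such as 0.29 to 0.37 without 1 library for Herpud1, -0.89 to -0.68 for Kif15 and 0.49 to 0.61 for Ier2.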

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

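All tests in this part were chosen after the results were seen. Between the tissue sets defined by anterior RNA, the change differed, by a test of the difference itself, in 202 genes for light damage against control and in 196 genes for A74 against light damage. These tests have arms of 1 library, which is assumed to vary like the others. The first rests on light damage replicate 3 and control replicate 3, the only libraries of the low set. The second rests on light damage replicate 3 and on A74 replicate 1, whose lens genes stood at 1023 CPM. Control replicate 3 was high in Xist and light damage replicate 3 was not. Among control and light damage libraries, the low set is also the set without Y transcripts. The difference between sets in the first test can therefore not be assigned to anterior RNA or to Y transcripts. For light damage against control, camera called 11 lists in this difference (high minus low set), none of them with an estimated correlation. The strongest calls were for rod genes (mean log2 difference -0.50, adjusted p = 4.36e-26, adjusted p = 0.439 with an estimated correlation) and interferon-stimulated genes (2.02, adjusted p = 1.10e-20, adjusted p = 0.405 with an estimated correlation). Antigen presentation (0.96), gliosis (0.33), microglia (0.44), lens (2.82) and pigment epithelium genes (-1.95) were also among the lists called with the preset correlation, with 0, 2, 0, 0 and 1 of their genes called. For A74 against light damage 12 lists were called, none with an estimated correlation, among them interferon-stimulated genes (-2.02, adjusted p = 9.81e-20, adjusted p = 0.399 with an estimated correlation), rod genes (0.43) and microglia genes (-1.05).

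Interferon-stimulated genes stood at 3.35 and 2.80 in light damage replicates 1 and 2 and at 1.12 in replicate 3, on the log2 scale relative to control. A weaker response of the whole library stays open: replicate 3 reached 36.5% of the rise in replicates 1 and 2 for this list, against 39.2% to 85.5% for the 15 other changed lists, with an SD of 12.7. RNA of anterior eye tissue that carries the transcripts and the absence of Y transcripts cannot be told apart from the library itself, because 1 light damage library was low in the former and the same 1 lacked the latter. The control and A74 libraries decide nothing here, since the list was not raised in them. No biological explanation was tested, since the design names no group within light damage.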

How the results depend on the processing

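The fits with tissue set or Y transcripts as terms, and the fit without light damage replicate 3 and A74 replicate 1, were chosen after seeing the data. Scaling by DESeq2's size factors kept every gene and list count within 1.5 times, and no fit reversed a named called gene. Gfap in A74 against control, not called, went from -0.31 to 0.0768 with Y transcripts as a term and 0.14 with both terms. The cause of these shifts was not tested except where fewer libraries or a stricter threshold set them.

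For light damage against control, 615 genes passed a 2-fold minimum, and 2818 to 5467 were called without 1 library. For A74 against light damage the counts were 481 with that minimum, 745 with Y transcripts, 810 with both terms, and 1717 to 4514 without 1 library. For A74 against control they were 16 with that minimum, 718 without a count filter, 296 with DESeq2, 558 with the 2 groups alone, 96 with Y transcripts, 291 with both terms, 934 without the 2 libraries, and 21 to 416 without 1 library.

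Lists called fell from 16, 18 and 5 to 0 in all 3 comparisons with an estimated correlation. With fry, 16 lists were called for light damage against control and 16 for A74 against light damage. Interferon-stimulated genes were not among them in either comparison. For A74 against control they were 9 without a filter, 2 with fry, 9 with tissue set, 13 with Y transcripts, 11 with both terms, and 2 to 6 without 1 library.

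Genes that moved back were 374 with a 2-fold minimum, 660 with Y transcripts, 669 with both terms and 1226 to 3478 without 1 library. The share of the light change left was 18.5% with a 2-fold minimum, 30.5% with tissue set, 41.6% with Y transcripts, 42.0% with both terms, 18.98% without the 2 libraries, 20.6% cross-fitted, and 18.7% to 27.9% without 1 library.

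The samples share only a replicate number: deviations of same-numbered libraries correlated from -0.09 to 0.31, not every sample correlated best with its own number (A74 replicate 2 did so with control replicate 3), and the submitters' library names carry other numbers. With the number as a replicate block, 4588, 3362 and 136 genes and 17, 18 and 4 lists were called, 2438 genes moved back and the share left was 24.0%. Of the named called genes, 59 of 59, 48 of 60 and 6 of 14 kept their call without each library. Il1b and Tnf, with at most 5 and 6 counts in a library, were too low to compare at this depth.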

Other observations

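The gene lists were fixed before the data were examined, and the tests of explanations and of splits in this part were chosen after the results were seen. Of 13 circadian clock genes 1 rose and 3 fell after light damage (camera adjusted p = 0.544), or 2 and 3 adjusted over the list alone, with the output gene Dbp at 0.37 (SE 0.06). With A74 against light damage 2 rose and 1 fell, Per1 among the former, and the list was not called (camera adjusted p = 0.350). Of 13 mitochondrially encoded genes 1 rose and 1 fell after light damage (camera adjusted p = 0.259), and none was called with A74 against light damage by edgeR. Of 11 extracellular matrix genes 3 rose after light damage (camera adjusted p = 0.0847) and 3 fell with A74 against light damage, or 4 adjusted over the list alone (camera adjusted p = 0.00446, adjusted p = 0.280 with an estimated correlation, fry adjusted p = 0.0530). Endoplasmic reticulum stress genes rose in 4 of 11 cases after light damage, also 4 adjusted over the list alone (camera adjusted p = 0.0771). The pigment epithelium list was lower with A74 than with light damage, with 1 of 9 genes called, or 0 adjusted over the list alone (camera adjusted p = 0.0118, adjusted p = 0.496 with an estimated correlation, fry adjusted p = 0.246). The lens list was not called (camera adjusted p = 0.0730). For the cone list, which camera did not call, the median after light damage was -0.06 and the mean 0.01, so their signs differed. No red blood cell gene of 4 was called in any comparison, nor was the 1 measured gene of the corneal epithelium list or of the T cell list, Lck. With 1 gene measured, adjustment over the list changes nothing, so Lck after light damage only had an unadjusted edgeR p under 0.05. In that comparison 6454 of 17272 genes had such a p. Csf3r, the only gene of the neutrophil list that passed the count filter, had a log2 fold change of -1.08 with A74 against light damage.

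Immediate-early genes were higher in both light groups than in control, with list means of 0.93 to 1.27 in the 6 light-exposed libraries, and 11 of the 12 genes lay above every control library in all 6. Anterior tissue as the whole cause is argued against, since the lowest mean change within either tissue set was 1.17. Handling that differed between control and light-exposed eyes cannot be told apart from light exposure, because the labels give all libraries the same batch and no handling.

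The movement of light-changed genes toward control with A74 runs along a difference in sex-linked transcripts. Y transcripts as an equal shift in every group are argued against as the whole cause. With them as a term 660 genes still moved back, against 2280 without it. That term cannot take up a light response whose size differs with Y transcripts, so it does not decide on such a response. Light damage replicate 3, without Y transcripts, stood at 55.5% of the change in replicates 1 and 2, over genes chosen without it. Replicates 1 and 2 both chose those genes and set the reference, which favours them. Part of the gap to replicate 3 may come from that choice. The A74 libraries stood at 17.9% to 21.7%, but replicate 3 is 1 library and, unlike them, was not high in Xist. Anterior tissue as an equal shift in every group is argued against as the whole cause by 2095 genes that moved back with tissue set as a term. A light response whose size differs between the tissue sets is not covered by that term. Xist expression of the A74 libraries cannot be told apart from A74, because 0 light damage libraries had over 100 Xist counts. A part of the difference may therefore come from the sex of the animals, which stays untested beside the treatment.

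Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. For light damage against control the real split called 4452 genes, as many as in 1 of the 10, and the highest other split called 2. For A74 against light damage the real count of 3153 was reached in 1, and the highest other was 16, in the split that follows the tissue set. The within-set values are 3196 genes in the high set and 677 in the low set. For A74 against control the real count of 154 was reached in 1, with 5 as the highest other, again in the split that follows the tissue set. Every other split holds libraries of both groups on each side, so the group difference itself enters the spread and lowers the calls. The low gene counts there therefore do not measure chance, and any difference along the groups would give them. Lists called with the preset correlation differed less between the real split and the others. They were 16 for light damage against control, reached in 3 of 10 splits with 17 as the highest other, 18 for A74 against light damage, reached in 1 with 16 as the highest other, and 5 for A74 against control, reached in 6 with 6 as the highest other.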
